A study of Mus musculus with 9 samples.

How the data were processed

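RNA from laser-microdissected regions of the mouse optic cup at E11.5 was hybridised to Affymetrix Mouse Genome arrays, 1 array per sample. The labels name 3 regions with 3 arrays each: the optic fissure, which took in cup cells within 5 cell diameters of the fissure edge, the centre of the nasal cup and the centre of the temporal cup. The series describes the 3 arrays of a region as biological replicates and letters them A, B and C. It does not say whether the 3 regions of a letter came from the same embryos, so p-values measure the spread between these samples.

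The deposited values are probe set intensities on a linear scale, with 45101 probe sets per array. How the authors summarised probes into probe sets and scaled the arrays is not given in the sources used here. In the deposited intensities, the mean after trimming 2% from each end lay at 150 on every array, so the arrays had been scaled to a common mean. Array medians ran from 27.4 to 30.2, a gap of 0.09 on the log2 scale, and the values were used without further scaling. No detection calls were used here. The number of arrays limits the precision of every value.

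Names came from the platform annotation table, which can be old. Of the probe sets, 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 were unnamed in that table. Symbols were checked against the RefSeq gene table of assembly GRCm38.p6 through the gene ID, and 0 needed updating. A gene was represented by its probe set with the highest mean over the 9 arrays, among probe sets with 1 symbol, which gave 18193 genes. Intensities were turned into log2(intensity + 16), and a gene was tested if it lay above the array's 40th percentile on at least 3 arrays, which left 12772 genes. Fold changes are on this log2(intensity + 16) scale and understate the change of dim genes.

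A linear model with 1 mean per region was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted over all tested genes by the Benjamini-Hochberg method. A gene passed at an adjusted p below 0.05. The 4 comparisons were fissure against the mean of nasal and temporal, fissure against nasal, fissure against temporal, and nasal against temporal. All adjusted p-values of genes below come from limma. Changes are given with their standard error (SE), and intensities as mean ± SD over 3 arrays.

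The letters were checked as a pairing. Deviations from the region means correlated at 0.167 to 0.486 across genes in the 9 pairs of arrays that share a letter, against -0.438 to 0.217 in the 18 pairs that do not. Every pair lay above the 0.1 set beforehand, so the letters were taken to pair the samples, on the evidence of the data and not of the labels. A fit with the letter as a block was run beside the fit without it, and its counts are printed beside those of each comparison and of the lists described for fissure against the mean of nasal and temporal where they differ by over 1.5 times. For the other comparisons blocked list counts are printed only for lists named there.

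The comparisons, the alternatives, the 31 gene lists and the rule for naming genes were fixed before the data were examined. The rule took the 12 genes with the largest change each way for fissure against the mean of nasal and temporal and for nasal against temporal, and 6 each way for the other comparisons, among genes past the threshold with regions that did not overlap. With fewer than 5 in a direction, the 5 with the smallest p were taken. It added 20 regional identity genes and up to 4 members of each list with the smallest p. Of the identity genes, 18 had a named probe set in the table, and the other 2 are not analysed here. The lists hold 736 genes, of which 679 had a probe set and 589 were tested. List shifts were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Counts of list members are given from the adjustment over all genes and, where stated, adjusted over the list alone.

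The fit was tested on simulated data in which 200 of 12772 genes were changed. For fissure against the mean of nasal and temporal, 0% of genes changed by 0.5 on the log2 scale were recovered, 85.5% of those changed by 1 and 100% of those changed by 2. For nasal against temporal, the shares were 0%, 80% and 100%. Alternatives covered the filter, the normalization, the pseudocount, the summary of probe sets, the variance model, array weights, the block, the regions in the fit and leaving out each array. Added after seeing the data were fits without the 3 arrays of letter B, with the Gapdh ratio of 3-prime to 5-prime signal as a covariate, and with the poly-A spike signal as a covariate. Figures were drawn with matplotlib 3.10.9.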

Results

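Transcript levels were measured in 9 samples of the mouse optic cup at E11.5, when the ventral margins of the cup face each other across the optic fissure. The design compares the fissure margin with the nasal and temporal cup, and the nasal with the temporal cup. Between 0 and 4 probe sets per array read 0, and the brightest probe set per array read 12794 to 17652. The first principal component held 43.2% of the variance and set the fissure arrays apart from the others, at -38.4, -9.30 and -42.8 against 4.56 to 29.4. Fissure array B stood apart from the other fissure arrays on the first component, at -9.30, and on the second, at 32.2, which held 20.9%. Its log2 values correlated at 0.971 and 0.964 with fissure arrays A and C. With the nasal arrays the correlations were 0.960 to 0.970, and with the temporal arrays 0.961 to 0.968, so it was about as like those as like fissure array C. The poly-A spike added during labelling read 1374 ± 650 in the fissure, 758 ± 286 in nasal and 652 ± 278 in temporal samples (SD, n = 3 each), and was highest in the fissure within each of the 3 letters. An exact two-sided permutation test of its log2 values over the 84 splits, which ignore the letters, gave p = 0.0714. The Gapdh ratio of 3-prime to 5-prime signal was 9.34 ± 5.13, 6.58 ± 1.98 and 6.19 ± 1.55 in fissure, nasal and temporal samples, and it too was highest in the fissure within each of the 3 letters (exact permutation p = 0.274, over splits that ignore the letters). In every region this ratio was lowest in letter B and the spike highest in letter C. The letters thus follow RNA measures as well, and need not mark embryos.

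The first comparison asks how the fissure margin differs from the rest of the cup. The largest rises included genes of the ventral cup. Vax1, a homeobox gene of the ventral eye and optic stalk, read 629 ± 91.7 in the fissure against 25.4 ± 15.8 in nasal and 40.7 ± 13.6 in temporal cup, a log2 change of 3.77 (SE 0.22, adjusted p = 3.18e-06). Ntn1, which encodes the secreted guidance protein netrin-1, read 270 ± 135 against 2.93 ± 2.76 and 12.2 ± 1.62 (log2 change 3.49, SE 0.29, adjusted p = 2.81e-05). At the lower end stood Cyp26a1, an enzyme that degrades retinoic acid, at 11.8 ± 1.90 against 284 ± 112 and 400 ± 165 (log2 change -3.60, SE 0.26, adjusted p = 1.36e-05). Fgf15, a growth factor gene of retinal progenitors, read 271 ± 49.2 against 1749 ± 214 and 1694 ± 222 (log2 change -2.60, SE 0.16, adjusted p = 3.18e-06).

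In all, 1101 of 12772 genes passed, 731 higher and 370 lower in the fissure, and 279 and 131 of them changed at least 2-fold. With the letter as a block the count was 2157, and all 1101 were among them. The groups of 14.1% of genes did not overlap, against 2.38% from chance if the letters are ignored. Without fissure array A the count was 544, without fissure array C 585 and without fissure array B 1707. With array weights it was 4076, 2617 higher and 1459 lower, and with the poly-A spike as a covariate, an alternative chosen after seeing the data, 440.

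On the log2(intensity + 16) scale, the other genes with the largest rise were Afap1l2 (312 ± 21.2 against 3.67 ± 3.41 nasal and 5.43 ± 3.77 temporal), Adamts16, a secreted metalloprotease, Smoc1, a matricellular protein, and Cyp1b1, a cytochrome P450. Their log2 changes were 4.01, 3.81, 3.75 and 3.55. Slitrk1, which encodes a neuronal membrane protein, rose from 2.80 ± 2.19 and 12.1 ± 6.97 to 166 ± 18.2. Cp, which encodes ceruloplasmin, and the Wnt receptor gene Ror2 rose by 2.81 and 2.67. Ctss and Mpeg1, genes of macrophages, rose by 2.92 and 2.88, and the lens crystallin gene Cryaa by 2.72. Adamts16 varied between fissure arrays (397 ± 228) and its probe sets differed in sign. The one used here read 6.30 ± 4.45 and 13.6 ± 3.35 in nasal and temporal cup. A dimmer one changed by -0.91 against the mean of nasal and temporal cup (adjusted p = 0.0280). It read 8.67 ± 9.12 in the fissure, below the 40th percentile of the arrays (15.7 to 17.5).

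The other genes with the largest fall included Cldn1, a tight junction gene (log2 change -3.08), the matrix gene Spon1 (-2.91), the protocadherin gene Pcdh17 (-2.72), Slc4a5 (-2.52) and Ano1 (-2.38). The semaphorin genes Sema3e and Sema3a fell by 2.38 and 2.33, Reln, which encodes reelin, by 2.33, and Dapl1 by 2.19. Reln read 459 ± 54.0 in the fissure against 2124 ± 231 and 2654 ± 318. Ttr, the transthyretin gene, changed by -2.30 (SE 0.56, adjusted p = 0.0252). Its adjusted p was 0.0702, 0.0525 and 0.0995 without fissure array A, B or C, 0.0546 without nasal array A and 0.0517 without temporal array B.

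**Figure D1:**
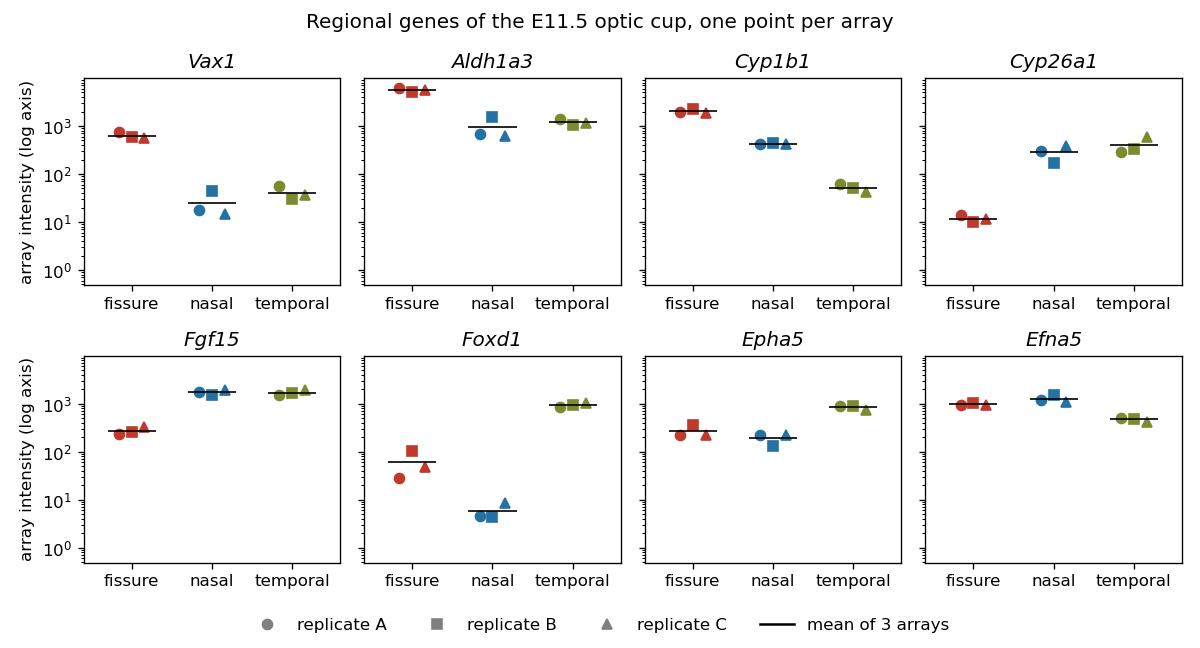
Array intensity (log axis) of 8 genes in the fissure, nasal and temporal cup, with 1 point per array, shaped by replicate letter, and a line at the mean of 3 arrays. Vax1 averages 629 in the fissure and 25.4 in nasal cup, Cyp26a1 averages 11.8 in the fissure and 400 in temporal cup, and Foxd1 averages 923 in temporal and 5.77 in nasal cup.

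Of 18 measured genes in the ventral cup and fissure list, 14 rose and 0 fell, with a median log2 change of 1.55 (camera adjusted p = 1.12e-18; adjusted p = 0.0246 with an estimated correlation). Adjusted over the list alone, 15 rose. Beside Vax1, Ntn1 and Cyp1b1, the retinol dehydrogenase gene Rdh10 rose from 513 ± 89.9 and 527 ± 22.3 to 1935 ± 178, and Vax2 from 315 ± 50.7 and 359 ± 66.0 to 744 ± 204. The list holds Adamts16, which may have been known from these same samples. That could not be checked in the sources used here, so that member is not taken as independent evidence of the direction. Nasal and temporal samples came from the centre of each side, so ventral position and nearness to the fissure change together in this design. Of 13 dorsal cup genes, 4 fell and 0 rose (camera adjusted p = 9.39e-04; adjusted p = 0.397 with an estimated correlation). They were the T-box genes Tbx2 (-1.51) and Tbx3 (-1.43), Bambi (-1.67), a decoy receptor of BMP signalling, and Msx2 (-0.75). Tbx5 (-0.54, adjusted p = 0.404), Bmp4 (-0.23, adjusted p = 0.761), Efnb2 (0.31, adjusted p = 0.382) and Aldh1a1 (-0.61, adjusted p = 0.187) did not pass. The dorsal count adjusted over the list alone was also 4.

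Genes of the nasal and temporal identity lists were mixed. Among 4 nasal identity genes Hmx1, a homeobox gene of the nasal retina, rose by 1.74 (adjusted p = 0.00270), and Efna5 (0.35, adjusted p = 0.176) did not pass (camera adjusted p = 0.661). Among 9 temporal identity genes, the transcription factor gene Nr2f1 (0.82) and the ephrin receptor genes Epha4 (1.05) and Epha3 (0.86) rose, and Foxd1 (-1.03) and Epha6 (-0.95) fell (camera adjusted p = 0.229). Foxd2 (-0.34, adjusted p = 0.239) and Epha5 (-0.59, adjusted p = 0.102) did not pass. Of the 9 temporal list genes, only Foxd1 and Epha5 differed between nasal and temporal cup in limma. Of the 4 nasal ones, Efna5 did, and Hmx1 only with the letter as a block. Epha3 averaged 45.4 in nasal and 42.7 in temporal cup. The rises of Nr2f1, Epha4 and Epha3 are therefore not evidence of temporal identity in the fissure. When adjusted over the list alone, 1 nasal identity gene rose, and 3 temporal identity genes rose and 3 fell.

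Of 16 genes of retinoic acid metabolism and response, 6 rose and 2 fell, and the list as a whole did not pass (camera adjusted p = 0.169). The synthesis gene Aldh1a3 rose from 941 ± 506 and 1182 ± 164 to 5583 ± 622 (log2 change 2.45, SE 0.25, adjusted p = 1.13e-04), Rdh10 rose by 1.87 and the retinoid receptor gene Rxrg by 1.52, while Cyp26a1 fell. Of 32 Wnt genes, 6 rose and 3 fell (camera adjusted p = 0.843), with Fzd1 (2.35), Dkk1 (2.13), Rspo3 (1.94) and Ror2 (2.67) higher. Of 30 BMP and TGF-beta genes, 5 rose and 3 fell (camera adjusted p = 0.914, with a median of -0.02 and a mean of 0.18). The receptor gene Bmpr1b rose by 2.06 and Id4 by 1.18. Of 17 FGF genes, 1 rose and 3 fell (camera adjusted p = 0.229, toward lower, with a median of 0.11 and a mean of -0.15). Fgf9, at 328 ± 77.9 against 545 ± 149 and 819 ± 71.7, and Fgf13 (-0.80) fell with Fgf15, and Dusp4 (0.86) rose. Among retinoic acid genes 7 rose and 2 fell adjusted over the list alone, with 6 and 4 among Wnt genes, 7 and 3 among BMP genes and 1 and 4 among FGF genes. In the blocked fit 8 BMP genes rose and 5 fell.

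Some cell cycle, progenitor and neurogenesis genes were lower in the fissure. In the same captures the median log2 changes of leukocyte, lens and mesenchyme genes were 1.54, 1.12 and 0.49. Of 38 cell cycle genes, 6 fell and 1 rose, with a median of -0.30 (camera adjusted p = 1.03e-07; adjusted p = 0.0165 with an estimated correlation), and 11 fell and 2 rose adjusted over the list alone. With the letter as a block 15 fell and 2 rose. Ccne1, which encodes cyclin E1, changed by -1.36, Cdc6 by -0.80 and Rrm2 by -0.70, and Cdkn1c, an inhibitor of cyclin-dependent kinases, rose by 0.75. Of 18 progenitor genes, 5 fell and 1 rose (camera adjusted p = 0.0197; adjusted p = 0.150 with an estimated correlation). Pax6 read 1565 ± 184 against 3199 ± 493 and 2835 ± 45.6, Hes5 changed by -1.93, and Meis2 rose by 1.23. Of 27 neurogenesis genes, 5 fell and 1 rose (camera adjusted p = 0.0122; adjusted p = 0.480 with an estimated correlation), with Neurog2 (-2.06), Neurod1 (-1.78), Insm1 (-1.27) and Sox11 (-0.72) lower. With p adjusted over the list alone, 5 progenitor genes fell and 2 rose, and 5 neurogenesis genes fell and 1 rose. With the letter as a block 6 progenitor genes fell and 3 rose.

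Pigment epithelium genes went both ways. Of 20 measured, 9 fell and 3 rose (camera adjusted p = 0.00190, toward lower; adjusted p = 0.397 with an estimated correlation), and 12 fell and 5 rose both adjusted over the list alone and with the letter as a block. Oca2, a melanosome transporter gene, read 215 ± 54.3 against 548 ± 75.4 and 620 ± 94.5, and Mlana changed by -1.63. The 3 that rose encode transcription factors. Tfec rose from 24.9 ± 5.10 and 26.3 ± 13.3 to 190 ± 26.5, Otx1 by 1.43, and Mitf by 0.93, the last named after its value was seen. Macrophage and leukocyte genes rose in the same captures (median log2 change 1.54). Which captured cells carry these 3 transcripts was not tested, so their rise need not be one in pigment epithelium.

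Among genes of the extracellular matrix, 7 of 27 rose and 2 fell (camera adjusted p = 0.0569). Lamb1, a laminin chain, rose from 440 ± 35.4 and 405 ± 47.6 to 1376 ± 320, the basement membrane gene Nid1 by 1.74, Sparc by 0.98 and Col9a2 by 1.46. Of 30 extracellular protease genes and inhibitors, 5 rose and 1 fell (camera adjusted p = 0.0412; adjusted p = 0.150 with an estimated correlation). They included Adamts16, Adamts5 (1.42), Adamts15 (1.28) and Adamts12 (0.72). Of 34 cadherin, integrin and adhesion genes, 6 rose and 6 fell (camera adjusted p = 0.914), with a median of 0.05 against a mean of -0.01 and a test toward lower, with Itga8 (1.90) higher and Itgb8 (-1.63) and Cdh8 (-1.48) lower. Of 43 Eph, ephrin and axon guidance genes, 10 rose and 6 fell (camera adjusted p = 0.914), with Plxnc1 (-1.78) lower. Of 41 genes linked to coloboma and eye malformation, 12 rose and 2 fell (camera adjusted p = 0.00240; adjusted p = 0.150 with an estimated correlation). Most of the genes that rose in this list are also in the ventral list, among them Vax1, Ntn1, Cyp1b1, Smoc1, Aldh1a3 and Tenm3. Its shift is therefore not separate from that of the ventral list. Among matrix genes 9 rose and 3 fell adjusted over the list alone, with 6 and 2 among proteases, 9 and 7 among adhesion genes, 10 and 7 among guidance genes and 14 and 2 among coloboma genes. In the blocked fit 7 protease genes rose and 2 fell.

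Markers of other cell types also differed. Of 17 macrophage and leukocyte genes, 15 rose and 0 fell, with a median of 1.54 (camera adjusted p = 1.12e-18; adjusted p = 0.0566 with an estimated correlation). Laptm5 rose from 43.9 ± 6.31 and 35.8 ± 12.1 to 277 ± 33.5, Ptprc, which encodes the leukocyte antigen CD45, by 2.02, and the complement genes C1qa and C1qb by 1.68 and 2.31. Of 10 lens genes, 5 rose and 1 fell (camera adjusted p = 0.00140; adjusted p = 0.150 with an estimated correlation), with Maf (2.24) and the crystallin genes Cryba1 (2.42) and Crybb1 (1.96) higher. Of 25 periocular mesenchyme genes, 7 rose and 2 fell (camera adjusted p = 0.00520; adjusted p = 0.496 with an estimated correlation). Eya2 (1.59) and Pdgfra (1.10) rose, and Postn (-1.43) and Dcn (-0.96) fell. None of 17 endothelial genes passed in limma without the block and 2 rose with it, and 3 had an unadjusted p below 0.05 (median 0.36; camera adjusted p = 0.0238; adjusted p = 0.566 with an estimated correlation). None of 8 erythroid genes passed in limma without the block and 4 rose with it, 5 had an unadjusted p below 0.05 and 3 passed adjusted over the list alone (camera adjusted p = 0.00920; adjusted p = 0.344 with an estimated correlation). Adjusted over the list alone, 15 leukocyte genes rose, 7 lens genes rose and 1 fell, 13 mesenchyme genes rose and 2 fell, and 0 endothelial genes passed. The embryonic globin gene Hbb-bh1 read 4588 ± 1128 against 2752 ± 1388 and 2987 ± 731 (adjusted p = 0.156, and 0.00720 with the letter as a block). With the block 12 mesenchyme genes rose and 2 fell.

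**Figure D2:**
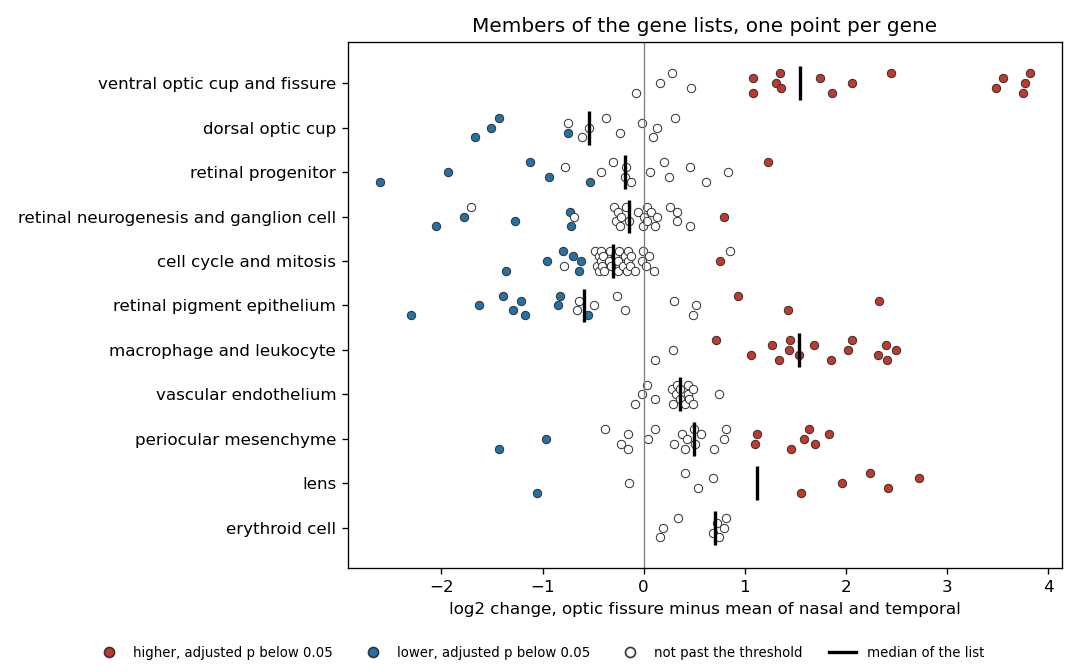
Log2 change of fissure minus the mean of nasal and temporal cup for the measured members of 11 gene lists, with 1 point per gene, filled where the adjusted p was below 0.05, and a bar at the list median. The medians are 1.55 for the ventral list, 1.54 for macrophage and leukocyte genes, 0.36 for endothelial genes and -0.30 for cell cycle genes.

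Of 13 surface ectoderm genes, 4 fell and 1 rose (camera adjusted p = 0.0340, and 0.0522 with the letter as a block; adjusted p = 0.150 with an estimated correlation). Krt8 and Krt18, the keratin genes of simple epithelia, changed by -1.89 and -1.33, Dsp, a desmosome gene, by -2.03, and Cdh1 rose by 0.87. Of 27 hypoxia and glycolysis genes, 3 fell and 2 rose (camera adjusted p = 0.00920; adjusted p = 0.135 with an estimated correlation), with Hk2 (-1.14) and Ldha (-0.62) lower and Ndrg1 (0.87) and Slc2a1 (0.57) higher. Of 24 immediate-early and stress genes, 4 rose and 0 fell (camera adjusted p = 0.145), among them Egr1 (1.36). The optic stalk and Hedgehog list had 1 riser of 12, Vax1 (camera adjusted p = 0.294). Of 21 apoptosis and engulfment genes, Gas6 (0.83) rose and Bcl2 (-1.11) fell (camera adjusted p = 0.254). Ednrb (0.95) rose and Kit (-1.11) fell among 6 melanocyte and neural crest genes (camera adjusted p = 0.833, toward lower, with a median of 0.06), and Wnt7b (1.01) and Emx2 (0.97) rose among 5 forebrain genes (camera adjusted p = 0.805, toward higher, with a median of -0.20). No ribosomal protein gene of 24 and no oxidative phosphorylation gene of 37 passed in limma, with 0 and 1 at an unadjusted p below 0.05 (camera adjusted p = 0.229 and 0.661). The oxidative phosphorylation list had a median of -0.01, a mean of 0.02 and a test toward lower. Adjusted over the list alone, 2 rose and 5 fell among ectoderm genes, 2 and 3 among hypoxia genes, 4 and 0 among stress genes, 3 and 2 among apoptosis genes, 2 and 2 among melanocyte genes and 2 and 0 among forebrain genes. In the blocked fit 3 optic stalk and Hedgehog genes rose, 4 apoptosis genes rose and 2 fell, and 2 melanocyte genes rose and 2 fell. Of the 31 lists, 15 passed with camera and 2 with an estimated correlation.

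The fissure was next compared with the nasal cup alone. The largest rises were in Afap1l2 (4.07), Adamts16 (4.03), Vax1 (4.02), Smoc1 (3.93), Ntn1 (3.78) and Slitrk1 (3.28). The largest falls were in Cldn1, at 20.2 ± 8.60 against 411 ± 69.1 (log2 change -3.57, SE 0.21, adjusted p = 5.85e-06), Cyp26a1 (-3.36), Spon1 (-2.88), Fgf15 (-2.63), Slc4a5 (-2.54) and Dsp (-2.37). The forkhead gene Foxd1 was higher in the fissure than in nasal cup, at 59.7 ± 38.3 against 5.77 ± 2.37 (log2 change 1.68, SE 0.29, adjusted p = 0.00450). Hmx1 read 643 ± 236 against 368 ± 169 and did not pass (log2 change 0.79, adjusted p = 0.215), nor did Efna5 (-0.35, adjusted p = 0.303).

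Of the tested genes, 810 passed, 559 higher and 251 lower, and 1579 passed with the letter as a block. The count was 414, 1234 and 458 without fissure array A, B or C and 432 without nasal array A, and it was 2650 with array weights, 423 at a 2-fold threshold and 410 with the poly-A spike as a covariate. In the ventral list 14 of 18 genes rose, and in the macrophage and leukocyte list 13 of 17 (camera adjusted p = 6.10e-20 and 1.29e-18; adjusted p = 0.0199 and 0.0576 with an estimated correlation). In the cell cycle list 4 of 38 fell and 1 rose (camera adjusted p = 5.39e-08; adjusted p = 0.0149 with an estimated correlation). Adjusted over the list alone, 15 ventral and 15 leukocyte genes rose, and 10 cell cycle genes fell and 2 rose. With the block 11 cell cycle genes fell and 2 rose. Of the 31 lists, 16 passed with camera and 2 with an estimated correlation.

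Against the temporal cup, Cyp1b1 had the largest change on the log2(intensity + 16) scale, which shrinks the folds of dimmer genes such as Afap1l2. It rose from 51.4 ± 8.80 to 2019 ± 209 (log2 change 4.92, SE 0.16, adjusted p = 2.60e-08). Afap1l2 (3.95), Adamts16 (3.60), Smoc1 (3.57), Vax1 (3.53) and Ntn1 (3.20) rose as well. Hmx1 rose from 82.5 ± 19.3 to 643 ± 236 (log2 change 2.69, SE 0.33, adjusted p = 5.79e-04) and Efna5, which encodes ephrin-A5, from 466 ± 46.8 to 982 ± 57.2 (1.05, adjusted p = 0.00310). The largest falls were in Cyp26a1 (-3.84), Foxd1 (-3.75), Pcdh17 (-3.09), Spon1 (-2.95), Neurog2 (-2.70) and Ttr (-2.65, adjusted p = 0.0343). The ephrin receptor gene Epha5 (-1.62) and Aldh1a1 (-1.18) also fell.

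Of the tested genes, 684 passed, 443 higher and 241 lower, and 1529 passed with the letter as a block. The count was 376, 1150 and 404 without fissure array A, B or C, 445 and 447 without temporal array A or B, 3122 with array weights, 390 at a 2-fold threshold and 276 with the poly-A spike as a covariate. The adjusted p of Ttr was 0.0825, 0.0588 and 0.109 without fissure array A, B or C and 0.116 and 0.124 without temporal array A or B. In the ventral list 13 of 18 genes rose, and in the macrophage and leukocyte list 12 of 17 (camera adjusted p = 9.32e-18 and 1.92e-19; adjusted p = 0.0281 and 0.05 with an estimated correlation). In the temporal identity list 3 of 9 genes fell and 0 rose (camera adjusted p = 0.0214, and 0.0565 with the letter as a block; adjusted p = 0.167 with an estimated correlation). Dorsal cup genes fell in 5 of 13 cases (camera adjusted p = 5.66e-05; adjusted p = 0.292 with an estimated correlation). Adjusted over the list alone, 14 ventral and 15 leukocyte genes rose, 3 temporal identity genes fell and 3 rose, and 5 dorsal genes fell. With the block 3 temporal identity genes fell and 3 rose. Of the 31 lists, 14 passed with camera and 2 with an estimated correlation; the ventral and cell cycle lists were the 2 that held in each fissure comparison.

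The calls of both pairwise comparisons overlapped. In both, 372 genes were higher in the fissure and 179 were lower, 551 in all. Independent lists of the same sizes would share 19.4 and 4.74 genes. In 100 simulations of noise alone, with both comparisons using the same simulated fissure arrays, 0.02 and 0 were shared on average. With no gene changed almost none can pass, so these simulations do not measure what the shared fissure arrays add. Part of the excess may come from the fissure arrays that both comparisons share. With the letter as a block 1107 were shared, and without fissure array A, B or C and without nasal array A the number was 303, 861, 333 and 356. Foxd1 was the 1 gene called in opposite directions, above the nasal and below the temporal cup.

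The last comparison asks which genes separate the nasal from the temporal cup. Foxd1, a forkhead gene of the temporal retina, read 5.77 ± 2.37 in nasal and 923 ± 77.7 in temporal cup (log2 change -5.43, SE 0.29, adjusted p = 7.25e-06). Cyp1b1 read 430 ± 4.44 against 51.4 ± 8.80 (log2 change 2.73, SE 0.16, adjusted p = 9.11e-06). Efna5 was higher in nasal cup, at 1265 ± 225 against 466 ± 46.8 (1.40, adjusted p = 0.0109), and its receptor gene Epha5 in temporal cup, at 190 ± 49.6 against 834 ± 102 (-2.07, adjusted p = 0.00740). The monoamine oxidase gene Maob was higher in temporal cup (-1.14, adjusted p = 0.0109) and 3110039M20Rik in nasal cup (1.61, adjusted p = 0.0192).

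These 6 genes were all that passed in limma, 3 each way, and 371 had an unadjusted p below 0.05. With the letter as a block 17 passed, 8 higher and 9 lower in nasal cup. The count was 10 with array weights, 16 with each probe set on its own and 3 with only the 2 regions compared. Among alternatives chosen after seeing the data, it was 11 with the Gapdh ratio as a covariate and 3 without the arrays of letter B. The groups of 6.78% of genes did not overlap, against 10% from chance if the letters are ignored. Since the letters were taken to pair the samples, that 10% does not apply as it stands, and the share cannot be read as below chance. Without nasal array B the count was 3, and without temporal array A, B or C it was 2, 2 and 3. Foxd1 and Cyp1b1 passed without each of the 9 arrays in turn, whereas the adjusted p of Epha5 was 0.0579 and 0.0635 without temporal array A or B. Efna5 missed without nasal array A or B (0.0559, 0.0515) and without temporal array A, B or C (0.0579, 0.0635, 0.0597). Maob missed without each of the 3 nasal and 3 temporal arrays, at 0.0515 to 0.0998, and 3110039M20Rik without nasal array B or C and each temporal array, at 0.0557 to 0.141.

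The next genes by smallest p did not pass without the block. Efhd1 (1.12, adjusted p = 0.0744) and A730056A06Rik (0.94, adjusted p = 0.110) were brighter in nasal cup, and Cdh9 (-1.47, adjusted p = 0.0744) and Tenm3 (-1.08, adjusted p = 0.0744) in temporal cup. With the letter as a block their adjusted p was 0.0225, 0.0422, 0.0159 and 0.0213, and that of Hmx1 was 0.0408 (log2 change 1.89, adjusted p = 0.132 without the block). Of 4 nasal identity genes, 1 passed (camera adjusted p = 1.75e-06; adjusted p = 0.0353 with an estimated correlation). Of 9 temporal identity genes, 2 passed (camera adjusted p = 1.17e-07; adjusted p = 0.0267 with an estimated correlation). No neurogenesis gene of 27 passed in limma, and the list lay toward temporal cup with a median of -0.26 (camera adjusted p = 9.89e-07; adjusted p = 0.256 with an estimated correlation). At an unadjusted p below 0.05 stood 1 neurogenesis gene brighter in nasal and 6 brighter in temporal cup. Neurog2 read 110 ± 60.3 in nasal and 278 ± 91.7 in temporal cup (adjusted p = 0.618, and 0.0132 with the letter as a block). The counts adjusted over the list alone were 2 nasal identity genes, 2 temporal identity genes, and 1 neurogenesis gene higher and 2 lower in nasal cup. With the block 2 nasal identity genes and 1 neurogenesis gene, Neurog2, passed. Of the 31 lists, 10 passed with camera, 2 with an estimated correlation and 3 with fry.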

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

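Probe sets that the annotation table used here does not tie to 1 gene entered no comparison above, and 5400 of them passed the filter on dim signal. Fitted together with all other probe sets in limma, 224 of these differed between the fissure and the mean of nasal and temporal cup, 119 higher and 105 lower in the fissure. Against the nasal cup 141 differed, against the temporal cup 133, and between nasal and temporal cup 7. They are given as counts only, and no explanation was tested.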

How the results depend on the processing

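The poly-A spike, the Gapdh ratio and the fits without letter B were chosen after seeing the data; the other alternatives were planned. Without fissure array A, B or C in turn, and without each nasal and temporal array, the count for fissure against the mean of nasal and temporal ranged from 544 to 1707, against nasal from 414 to 1234, against temporal from 376 to 1150, and for nasal against temporal from 2 to 8. Shared calls ranged from 303 to 861, and lists past the threshold from 11 to 16, 11 to 17, 11 to 15 and 7 to 11 in the order of the 4 comparisons. Fewer arrays lower the power of each such fit; the rise without fissure array B goes against that, and its cause was not tested. In the order of the 4 comparisons, the letter as a block gave 2157, 1579, 1529 and 17 genes and 1107 shared calls, array weights gave 4076, 2650, 3122 and 10, and for the first 3 a 2-fold threshold gave 410, 423 and 390. With array weights and the block, the cause was not tested. The poly-A spike as a covariate gave 440, 410 and 276 for the fissure comparisons. For nasal against temporal, each probe set on its own gave 16 (more features tested), the Gapdh ratio as a covariate 11, only the 2 regions compared 3, and leaving out the 3 arrays of letter B 3 genes and 5 lists. The causes were not tested. Camera with an estimated correlation left 2 lists in each of the 4 comparisons, out of 15, 16, 14 and 10. They were the ventral and cell cycle lists for the fissure and the nasal and temporal identity lists for the last. For some lists that lost their call the estimate lay below the preset 0.01, such as the progenitor list in the first comparison (-0.035). A higher correlation therefore does not account for every lost call. With fry, 3 lists passed for nasal against temporal. Counts under the filters, normalizations, pseudocount and variance model stayed within 1.5 times. No named gene reversed direction past the threshold under the filters, normalizations, variance model, array weights, block or leaving out each array. No list did in the alternatives in which lists were tested. Named genes were not followed under the other alternatives, among them the pseudocount, the summaries of probe sets and the covariates. Taken on its own, the dimmer Adamts16 probe set changed by -0.91, past the threshold and against the one used here. For named genes of the first comparison, 2019 of 2134 alternative values kept direction and side of the threshold, 69 lost the call, 44 gained one and 2 turned sign without a call. Against nasal 97 of 2037 values lost the call, against temporal 121 of 1959, and for nasal against temporal 18 of 2001. In that order 45, 46 and 12 gained a call, and 9, 3 and 16 turned sign without one. A gene removed by a stricter filter has no value there. Genes near the dim end, below about the 40th percentile of 15.7 to 17.5 intensity units, have little signal over background. The simulated data, with 200 genes changed, recovered 0% of changes of 0.5 on the log2 scale. Far more genes passed in the real fissure comparisons, which eases the adjusted threshold, so that 0% does not carry over to them.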

Other observations

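Genes of the nasal and temporal contrast differed in where the fissure stood, a grouping made after the values were seen. Tenm3, a gene of teneurin adhesion proteins, read 2882 ± 163 in the fissure, 793 ± 104 in nasal and 1706 ± 302 in temporal cup (SD, n = 3 each), and rose in the fissure against both. Maob read 377 ± 19.6 in the fissure, beside 342 ± 15.5 in temporal cup (limma adjusted p = 0.671), and was higher there than the 146 ± 9.03 of nasal cup (log2 change 1.28, limma adjusted p = 2.32e-04). 3110039M20Rik read 12.2 ± 3.29 in the fissure and 12.9 ± 3.55 in temporal cup (limma adjusted p = 0.958) against 74.3 ± 26.8 in nasal cup.

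The tests of endothelial genes against the leukocyte list, of the size of the fold changes under the spike covariate, of the pigment epithelium genes and of the splits within letters were chosen only after the results they measure were seen, and the fits with the Gapdh ratio and the poly-A spike as covariates were added after the data and the 1101 calls were seen.

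The leukocyte genes raised in the fissure were followed with a second list of 21 leukocyte genes, written before their values were seen. None was in the first list, and the list was meant to lie outside engulfment. Whether each member does, for example Rac2 or Cybb, was not checked. Of 14 measured, 11 rose and 0 fell (median log2 change 1.15), among them Ly86, Lcp1, Plek and Cd53. Engulfment genes switched on in retinal cells without leukocytes are argued against only as far as those members lie outside engulfment. Endothelial genes lay 1.18 below the leukocyte list in median log2 change (permutation p = 1.6e-04, with genes exchanged between the lists). Genes within a list are correlated, so that p does not measure the spread between samples. Extra tissue need not hold each cell type in equal parts. The difference therefore speaks only against extra tissue that raised both lists alike, and lens and mesenchyme genes rose too. Leukocytes captured with the fissure tissue remain a candidate explanation, by those 11 genes. Whether they lie within the fissure margin or in the mesenchyme beside it stays open, as does the share of RNA they brought.

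The 1101 calls of fissure against the mean of nasal and temporal cup were weighed against RNA quality. With the Gapdh ratio as a covariate 81.7% of the calls stayed past the threshold. That meets the rule written before that fit against 3-prime bias as the cause of most calls. However, this ratio was highest in the fissure within each letter, so it overlaps with region. It was also lowest in letter B in every region, so its slope partly follows the letters. The Gapdh fit therefore does not decide whether 3-prime bias made the calls. With the poly-A spike as a covariate 37.7% stayed, which meets the rule written before that fit for a lower RNA input in the fissure captures. The fold changes did not shrink: their median ratio with to without the covariate was 0.97 (quartiles 0.841 and 1.09), all 1101 kept their sign, and the median SE rose from 0.17 to 0.22, so calls ended through a wider error. Within every region the spike rose from letter A to B to C, so the slope of this covariate cannot separate input from letter. The fit therefore does not decide whether input made the fold changes. The spike was also highest in the fissure in each letter, so input and region overlap in this design. Lower input and a biological difference between regions both stay open.

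Pigment epithelium genes lower in the fissure might reflect fewer pigment cells in those captures. For the 9 members that fell, the spread around their common log2 change of -1.04 exceeded their errors (chi-square p = 5.3e-05). Expression of some members in other captured cells could give unequal falls too, and which cells express them was not tested. For those 9, fewer pigment cells and lower expression per cell cannot be told apart. The 9 were selected for having fallen, which limits the test further.

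Other splits of the arrays were counted for each comparison. For fissure against the mean of nasal and temporal, 1 of 100 splits, the real one, gave as many as 1101 genes, and the highest other gave 96, but most of these splits ignore the letters. The letters allow 27 choices of 1 array per letter as the fissure group, and with the other 6 arrays as 1 group the real choice gave 1204 genes and the highest other 2. That is 1 of 27, a share of 0.037, the smallest these choices can give. Every other choice puts at least 1 fissure array in the comparison group, which widens the spread there. The test alone therefore cannot exclude chance. For each pairwise comparison, 1 of 10 splits, the real one, reached the real count, which is too few for a share under 0.05. The real counts were 810, 684 and 6 for fissure against nasal, fissure against temporal and nasal against temporal, and the highest other split gave 0 in each.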
